A study of Mus musculus with 48 samples.

How the data were processed

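RNA of 48 samples of mouse embryo fibroblasts, 6 for each of 2 genotypes and 4 treatments, had been hybridised as biotin-labelled cRNA to Affymetrix mouse GeneChip arrays. The authors made the deposited intensity values with Affymetrix GCOS 1.4, per the labels. These are on a linear scale with 0 zero or negative values, and the arrays had been scaled to nearly one level, since the trimmed mean (2% left out at each end) ranged from 256.2 to 268.1. The algorithm and its target value are not given in the sources used here. The intensity was taken as log2(value + 1). Of the probe sets, 64 Affymetrix controls were left out of the tests and 45037 were tested. The platform annotation gave 34945 of them 1 gene symbol (18193 genes), 932 several symbols and 9160 none, and no gene is named from a probe set with several. The array's genome build is not named, so no coordinates are given. Genotype, treatment and replicate number were taken from the labels.

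A linear model with 1 mean per group over all 48 arrays (40 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in the mean level. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested probe sets of a comparison, with a threshold of 0.05. The 14 comparisons were each stimulus against mock in each genotype, both cytokines against TNFa in each genotype, CIKS-deficient against wild-type mock cells, the genotype differences of these responses as interactions, and the departure from additivity in each genotype. Errors of log2 fold changes are standard errors from this fit, and errors of levels are standard deviations. The level of Traf3ip2 and the mean level of each cell type list were compared between genotypes with two-sided exact permutation tests.

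Genes are named by a rule. They passed the threshold on a probe set with 1 symbol, had a mean level, in the highest of the groups compared, at or above the median of all probe sets of that group and, in comparisons of 2 groups, had no overlap between the 6 values of each group, which chance gives with a probability of 0.00216. Up to 12 higher and 8 lower genes with the largest changes were taken per comparison, and Traf3ip2 and members of the gene lists may also be named. The 27 gene lists covered inflammation and signalling, matrix and contractile genes, markers of other cell types, and growth, stress, HOX and sex-linked genes, each gene read through its probe set with the highest mean level. Lists were tested with limma's camera with a preset correlation between genes of 0.01, and again with an estimated correlation, adjusted over the 27 lists of a comparison. The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were pseudocounts of 16 and 64, a filter on dim probe sets, median centring, quantile normalization, array weights, no variance trend, a fit to the compared groups alone, the replicate number as a block, leaving out each array in turn and, for lists, the mean of all probe sets of a gene. A block on sets of arrays found in the data and the list tests without each array in turn were added after the data were seen.

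The fit was tested on simulated data with 50 probe sets changed at each size in a comparison of 6 arrays with 6. It recovered 46% of those changed by 0.5 on the log2 scale, 82% at 1, 96% at 1.5 and 100% at 2, and 2 of 164 calls were false. For an interaction it recovered 29 of 50 at 1 and 48 of 50 at 2. The simulated noise was independent between arrays and between probe sets, and the changed probe sets had a mean level at or above the median. These rates therefore do not cover dim probe sets or arrays that resemble each other in sets, as the real arrays did. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.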

Results

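Gene expression was measured in mouse embryo fibroblasts, connective tissue cells grown out of embryos and cultured in vitro. The cells came from wild-type mice and from mice deficient in CIKS, also called Act1, the adaptor that couples the IL-17 receptor to NF-kB signalling and that is encoded by Traf3ip2. Cells of each genotype were left unstimulated (mock) or were given IL-17, TNFa or both cytokines, and were lysed after 2 hours. The 48 arrays formed 8 groups of 6, and each array reported the brightness of 45037 probe sets beside 64 control probe sets. The highest intensity on an array ranged from 8301 to 21844, and the trimmed mean from 256.2 to 268.1. The 3' to 5' ratio of the GAPDH control probe sets, a sign of RNA integrity, ranged from 0.867 to 1.47, with the highest value on WT mock replicate 1. The number of arrays limits the precision of every value below. The labels do not say whether the replicates of a group were separate cultures or animals, so the p-values measure the spread between these samples. Arrays of different treatments also fell into sets that the labels do not name, and a fit with these sets as a block, chosen after the data were seen, called 641 probe sets (296 higher and 345 lower) in place of 73 (63 higher and 10 lower) for TNFa and 12 in place of 3 for IL-17 in wild-type cells. The comparisons ask which genes each cytokine changed and whether that change required CIKS.

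Traf3ip2, the gene the knockout removes, was lower on all 6 CIKS-deficient arrays than on any wild-type array within each treatment. Its single probe set had a mean log2 level of 7.23 ± 0.27 (SD, n = 6) on CIKS-deficient mock arrays and 7.97 ± 0.23 (SD, n = 6) on wild-type mock arrays. The difference was -0.74 in mock, -0.78 with IL-17, -0.65 with TNFa and -0.88 with both cytokines. A two-sided exact permutation test gave p = 0.00216 in each treatment, the smallest value that 6 against 6 arrays allow. The signal on CIKS-deficient arrays was 54.5 to 63.8% of that on wild-type arrays. Where this probe set lies relative to the deleted part of the gene is not given in the sources used here, so the remaining signal does not measure remaining CIKS.

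IL-17 alone raised 2 named genes in wild-type cells. Zc3h12a, which encodes the RNase Regnase-1 that degrades inflammatory transcripts, rose by a log2 fold change of 2.26 ± 0.33 (SE, n = 6 per group). Nfkbiz, which encodes the nuclear protein IkB-zeta, rose by 1.63 ± 0.18 on the probe set with its highest mean level, called its first here, and by 1.96 ± 0.18 on a second. The neutrophil chemokine Cxcl1 had a log2 fold change of 2.17 ± 0.52, the chemokine Ccl20 2.02 ± 0.59 and the cytokine Il6 1.26 ± 0.41, none of which passed the threshold over all probe sets. The limma test with Benjamini-Hochberg adjustment called 3 probe sets of 45037, all higher, with adjusted p = 0.000298 for Zc3h12a and 1.31e-07 for Nfkbiz. The third Nfkbiz probe set disagreed with the other 2, at 0.11 ± 0.12. A second Zc3h12a probe set stood at 0.75 ± 0.21 and did not pass. When the fit held only the wild-type IL-17 and mock arrays, Zc3h12a no longer passed (limma adjusted p = 0.127). With the block on the sets 12 probe sets were called, all higher, and those added were of Cxcl1, Il6, Relb, Ccl7, Fgf7 and Micall2, named after their values were seen.

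Of 31 measured genes linked to the IL-17 response, 2 rose in wild-type cells given IL-17 when all probe sets were adjusted together. Adjusted over the list alone, 5 rose: Nfkbiz, Zc3h12a, Il6, Cxcl1 and Ccl20. The list as a whole shifted upward in limma's camera test (adjusted p = 2.47e-11), with adjusted p = 0.187 with an estimated correlation. Of 30 NF-kB feedback and target genes, 1 rose over all probe sets. Adjusted over the list alone, 5 rose, among them the NF-kB subunit Relb (0.82 ± 0.22), the inhibitor Nfkbie (0.88 ± 0.32) and Bcl3 (1.00 ± 0.34). Camera gave that list adjusted p = 5.89e-08, and adjusted p = 0.106 with an estimated correlation. Among 16 regulators of mRNA decay, Zc3h12a rose, and adjusted over the list alone Rc3h1, which encodes Roquin-1, rose too (0.24 ± 0.08). The preset test gave this list adjusted p = 0.0066, and adjusted p = 0.0871 with an estimated correlation. Its median log2 fold change was 0.00229, and -0.00636 without WT mock replicate 1, against a mean of 0.196. The call thus does not show a shift of the typical member. For the 6 neutrophil-attracting ELR+ CXC chemokines the median log2 fold change was 0.68, with 0 called over all probe sets (6 above 0) and 1, Cxcl1, adjusted over the list alone. That list had a camera adjusted p = 0.000131, and adjusted p = 0.0871 with an estimated correlation. The preset test called these 4 lists without any 1 of the 12 arrays as well. The lists share genes that rose: the IL-17 response list shares Nfkbiz with the NF-kB list, Zc3h12a with the mRNA decay list and Cxcl1 with the ELR+ list. Calls of these lists, here and below, are therefore not independent of each other. Of markers of other cell types, all 14 cartilage markers had a log2 fold change below 0 with IL-17, with a median of -0.31, 0 members called, camera adjusted p = 0.0083 and adjusted p = 0.599 with an estimated correlation. They were not called without WT mock replicate 2, 4 or 5 or WT IL17 replicate 3 or 4, with a median of -0.13 without WT IL17 replicate 3.

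In CIKS-deficient cells IL-17 changed no probe set past the threshold. Nfkbiz on its first probe set stood at a log2 fold change of -0.05 ± 0.18, Zc3h12a at 0.02 ± 0.33, Cxcl1 at 0.06 ± 0.52 and Il6 at -0.16 ± 0.41 (SE, n = 6 per group). The limma test called 0 probe sets, and 1122 had an unadjusted p under 0.05. The difference between genotypes in the IL-17 response was itself tested as an interaction. Nfkbiz differed on 2 probe sets, by 1.68 ± 0.25 (the first, limma adjusted p = 0.000537) and 1.89 ± 0.26 (the second, adjusted p = 0.000166), and these were the 2 probe sets called by the fit without the sets. With the block on the sets 8 were called, all higher in wild-type cells: these 2, 1 of Zc3h12a (limma adjusted p = 4.92e-06), 3 of Cxcl1, 1 of Il6 (adjusted p = 0.0174) and a dim one with no gene symbol. Without the block Zc3h12a differed by 2.24 ± 0.47 without passing over all probe sets (limma adjusted p = 0.217), and passed when adjusted over the list alone of IL-17 response genes (adjusted p = 0.000299). Cxcl1 differed by 2.12 ± 0.73 and Il6 by 1.42 ± 0.58, and neither passed over all probe sets. Of the 31 IL-17 response genes, 1 differed over all probe sets and 2 adjusted over the list alone; camera gave adjusted p = 8.86e-07, and adjusted p = 0.459 with an estimated correlation. The cartilage markers had a median difference of -0.31 (camera adjusted p = 0.0323, and adjusted p = 0.803 with an estimated correlation), and were not called without WT mock replicate 1, 2, 4 or 5, WT IL17 replicate 3, 4 or 5, KO mock replicate 1, 4 or 5 or KO IL17 replicate 3 or 5 (median -0.17 without WT IL17 replicate 3). In CIKS-deficient cells the only list called against mock was that of immediate-early and MAPK-responsive genes, lower with a median of -0.11 (camera adjusted p = 0.0047), with adjusted p = 0.996 with an estimated correlation. It was not called without KO mock replicate 3 (median 0.02, adjusted p = 0.907) or without KO IL17 replicate 5 (median -0.05, adjusted p = 0.655). With only the 4 groups compared in the fit, the interaction was called for 1 probe set of Nfkbiz, and the first one had a limma adjusted p = 0.0758.

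**Figure D1:**
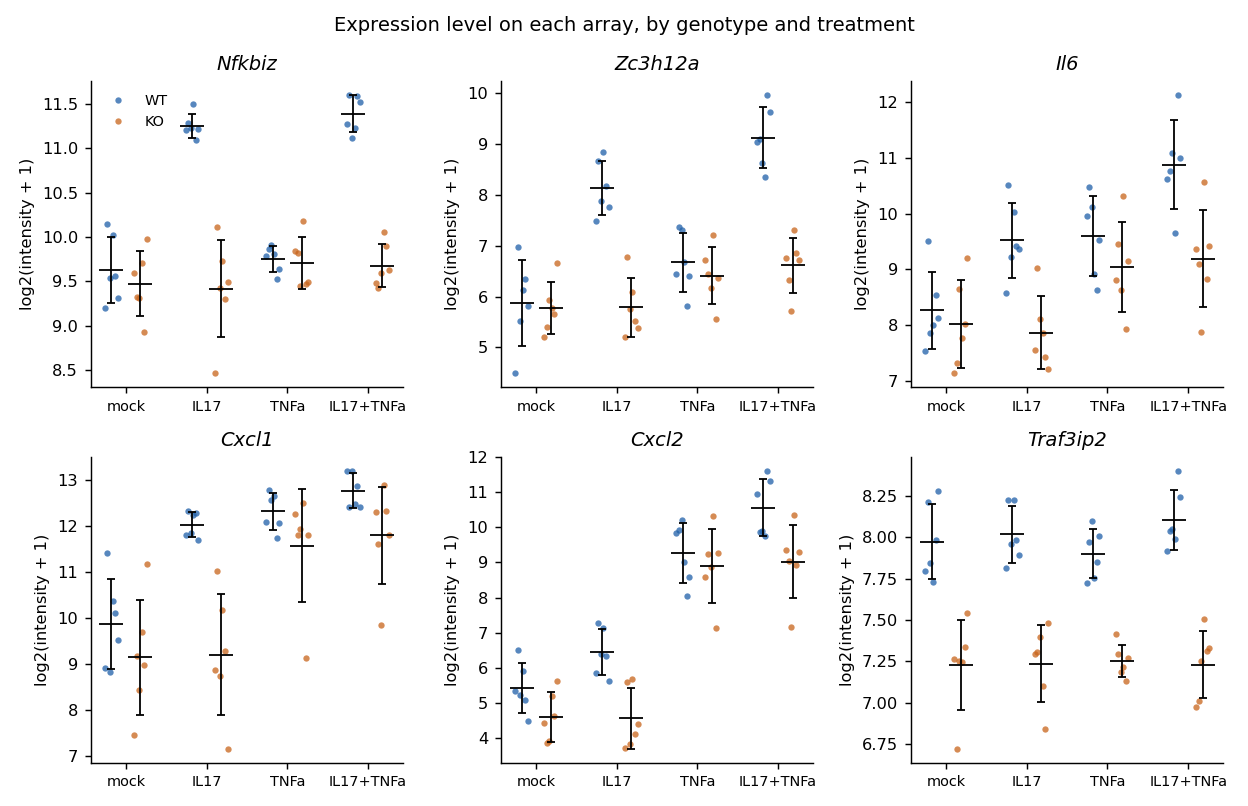
Level of 6 genes on each array as log2(intensity + 1), by treatment on the horizontal axis and genotype by colour (WT wild type, KO CIKS-deficient); each point is 1 array, the horizontal mark the group mean and the bar 1 SD, n = 6 per group. Nfkbiz had a mean of 11.25 on wild-type IL-17 arrays and 9.42 on CIKS-deficient IL-17 arrays, while Traf3ip2 was lower on CIKS-deficient arrays in every treatment.

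TNFa raised chemokine genes in wild-type cells. Of these, Ccl20 (log2 fold change 3.97 ± 0.59), Cxcl2 (3.85 ± 0.47), Cxcl10 (3.14 ± 0.37), Cxcl1 (2.46 ± 0.52) and Ccl2 (2.22 ± 0.34) rose (SE, n = 6 per group). Nfkbie, an inhibitor of NF-kB, rose by 3.06 ± 0.32, and Tnfaip3, which encodes the ubiquitin-editing enzyme A20 that limits NF-kB signalling, by 2.60 ± 0.29. The adhesion molecule E-selectin (Sele, 2.13 ± 0.34), the NF-kB subunit gene Relb (1.88 ± 0.22), the growth factor gene Pdgfb (1.76 ± 0.17), the apoptosis inhibitor Birc3 (1.72 ± 0.17) and the cytokine Lif (1.61 ± 0.23) also rose. Sele was dim in mock, at a log2 level of 3.78 ± 0.49 (SD), and with a pseudocount of 64 its change in WT TNFa vs mock was 0.69. Lower genes changed less: Zfp467 by -0.87 ± 0.19, Runx1t1, a transcriptional corepressor, by -0.72 ± 0.13, Rgs2, a regulator of G protein signalling, by -0.70 ± 0.15, and Mn1 by -0.62 ± 0.10. The limma test called 73 probe sets, 63 higher and 10 lower, where the block on the sets found in the data gave 296 higher and 345 lower, and 40 genes met the naming rule, under which the 6 values of each group did not overlap. Limma adjusted p was 0.0223 for Zfp467 and lower for the other genes given above. Zfp467 did not pass with array weights (limma adjusted p = 0.119). Other genes that fell were 2610008E11Rik (-0.68), Zfp628 (-0.50) and Dlg3 (-0.42), each of which lost the call when only the wild-type TNFa and mock arrays were fitted, which called 46 probe sets.

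Of 30 NF-kB feedback and target genes, 12 rose and 0 fell in wild-type cells given TNFa, and 19 rose adjusted over the list alone (camera adjusted p = 1.82e-48, held at adjusted p = 1.34e-06 with an estimated correlation). Of the 6 ELR+ CXC chemokines, 3 rose on either count: Cxcl1, Cxcl2 and Cxcl3 (camera adjusted p = 5.1e-11, and adjusted p = 0.000401 with an estimated correlation). Among 19 other chemokines 3 rose, and 5 adjusted over the list alone (camera adjusted p = 8.98e-13, and adjusted p = 0.0102 with an estimated correlation). Of 27 inflammatory cytokines and growth factors 2 rose, and 5 adjusted over the list alone: Il6, Lif, Csf1, Tnfsf11 and Inhba (camera adjusted p = 1.37e-10, and adjusted p = 0.00405 with an estimated correlation). The IL-17 response list had 4 members higher, and 6 adjusted over the list alone (camera adjusted p = 3.5e-21, and adjusted p = 0.0187 with an estimated correlation). Nfkbiz (0.13 ± 0.18) and Zc3h12a (0.79 ± 0.33) were not among them in the fit without the sets. Immediate-early genes had 2 members higher, Junb (0.80 ± 0.17) and Myc (0.40 ± 0.09), and 6 adjusted over the list alone; camera gave adjusted p = 3.08e-10, and adjusted p = 0.0553 with an estimated correlation. Of 18 p53 targets, 2 rose, the death receptor gene Fas (1.61 ± 0.26) and Plk2 (0.40 ± 0.08), and Sesn1 fell adjusted over the list alone (-0.42 ± 0.13), with camera adjusted p = 0.0127 and adjusted p = 0.469 with an estimated correlation. Of 33 measured HOX genes 0 fell over all probe sets and 4 fell adjusted over the list alone, Hoxa9 (-0.63 ± 0.15), Hoxa10, Hoxa11 and Hoxd9, with camera adjusted p = 0.00134 and adjusted p = 0.39 with an estimated correlation. The HOX list was not called without WT TNFa replicate 6 (adjusted p = 0.052), nor the p53 targets without WT mock replicate 1 or 2 or WT TNFa replicate 1, 3 or 4 (adjusted p up to 0.179).

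In CIKS-deficient cells TNFa raised chemokine genes and NF-kB feedback genes too. Ccl20 rose by 4.63 ± 0.59, Cxcl2 by 4.31 ± 0.47, Nfkbie by 3.39 ± 0.32, Cxcl10 by 2.94 ± 0.37 and Tnfaip3 by 2.55 ± 0.29 (SE, n = 6 per group). Ccl2 (2.44 ± 0.34), Sele (2.35 ± 0.34), Pdgfb (2.07 ± 0.17), Relb (2.05 ± 0.22), Birc3 (2.04 ± 0.17), the small GTPase gene Rnd1 (1.99 ± 0.31) and Cd83 (1.77 ± 0.30) rose too, and Zfp503 fell by 0.88 ± 0.19. The limma test called 81 probe sets, 79 higher and 2 lower, and 52 of the higher ones were also among the 63 higher in wild-type cells, where independent lists would share 0.111. The lists of the genotypes share 1 estimate of the spread per probe set, so this figure and those like it below may be too low for chance. Of the 63, 62 had a positive fold change in CIKS-deficient cells, with a median of 1.20 against 1.12 in wild-type cells. Of the 10 lower in wild-type and the 2 lower in CIKS-deficient cells 1 was shared, where independent lists would share 0.000444, and the 10 had a median of -0.65 in wild-type and -0.39 in CIKS-deficient cells. The 2 had a median of -0.656 in CIKS-deficient and -0.518 in wild-type cells, so each list fell more in the genotype that selected it. With the block on the sets 274 were higher and 70 lower in CIKS-deficient cells, of which 200 and 46 were shared with the 296 and 345 in wild-type cells, where independent lists would share 1.8 and 0.536. The test of the genotype difference in the TNFa response called 0 probe sets by limma, and 1053 had an unadjusted p under 0.05. Among NF-kB feedback and target genes 14 rose, and 19 adjusted over the list alone (camera adjusted p = 1.22e-80, and adjusted p = 2.7e-09 with an estimated correlation). Cxcl1, Cxcl2 and Cxcl3 rose among the 6 ELR+ CXC chemokines on either count (camera adjusted p = 2.9e-19, and adjusted p = 2.12e-06 with an estimated correlation). With only the groups compared in the fit the count was 37, and with median centring Zfp503 did not pass (limma adjusted p = 0.0524).

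**Figure D2:**
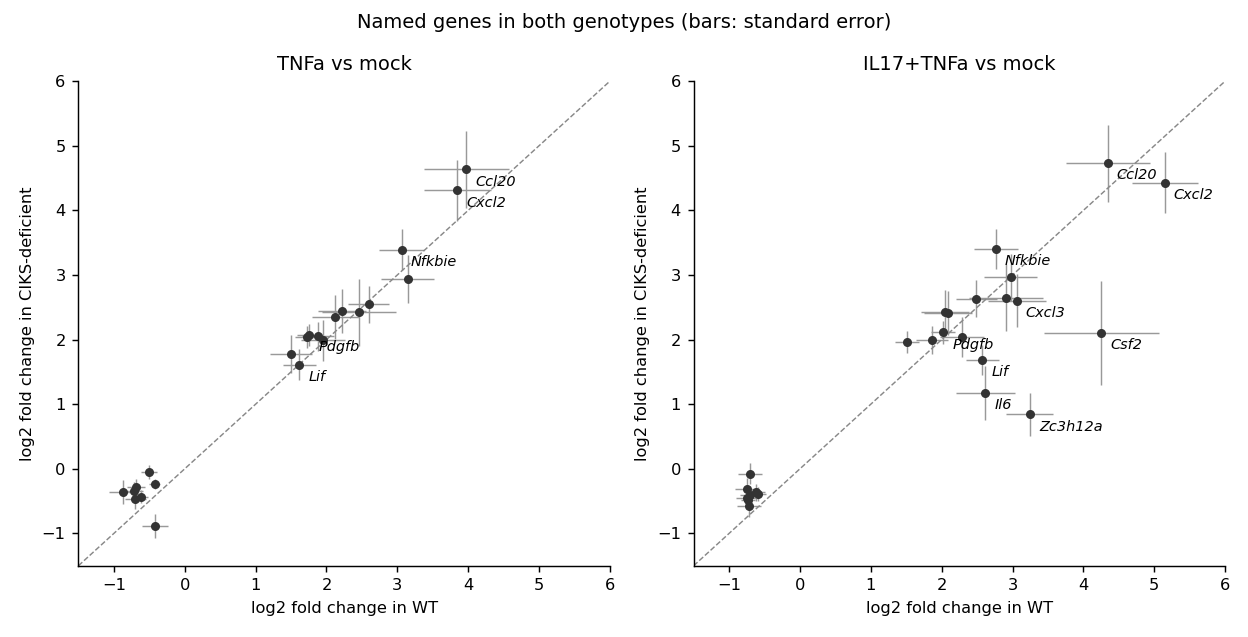
Log2 fold change of the named genes in wild-type cells (horizontal axis) against CIKS-deficient cells (vertical axis), for TNFa against mock and for both cytokines against mock; points are genes, bars are standard errors and the dashed line marks equal change. With both cytokines, Zc3h12a lies at 3.24 in wild-type and 0.84 in CIKS-deficient cells, and Il6 at 2.62 and 1.18.

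Both cytokines together gave the longest list of called probe sets of the 14 comparisons in wild-type cells. Cxcl2 rose by a log2 fold change of 5.15 ± 0.47, Ccl20 by 4.34 ± 0.59, the granulocyte-macrophage growth factor gene Csf2 by 4.25 ± 0.81, Zc3h12a by 3.24 ± 0.33 and Cxcl3 by 3.06 ± 0.41 (SE, n = 6 per group). Cxcl10 (2.97 ± 0.37), Cxcl1 (2.91 ± 0.52), Nfkbie (2.77 ± 0.32), Il6 (2.62 ± 0.41), Lif (2.58 ± 0.23), Tnfaip3 (2.49 ± 0.29) and Rnd1 (2.29 ± 0.31) followed. Genes that fell were Sertad4 (-0.75 ± 0.16), Rgs2 (-0.75 ± 0.16), Mn1 (-0.73 ± 0.10), 9930012K11Rik (-0.72 ± 0.17), the circadian transcription factor gene Dbp (-0.70 ± 0.15), Fam53b (-0.70 ± 0.17), Runx1t1 (-0.62 ± 0.13) and Jade1 (-0.59 ± 0.11). The limma test called 138 probe sets, 120 higher and 18 lower, where the block on the sets gave 690, 436 higher and 254 lower. Csf2, a dim probe set with a mean log2 level of 1.63 ± 0.32 (SD) in mock, had a log2 fold change of 1.16 and a limma adjusted p = 0.0947 with a pseudocount of 64. The count was 81 when only these 2 groups were fitted, where Rgs2, 9930012K11Rik, Fam53b and Runx1t1 did not pass, and with median centring Sertad4, 9930012K11Rik and Fam53b did not.

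In this comparison 14 of 30 NF-kB feedback and target genes rose, and 21 adjusted over the list alone (camera adjusted p = 3.49e-71, and adjusted p = 1.39e-08 with an estimated correlation). Of the 31 IL-17 response genes 9 rose, and 14 adjusted over the list alone, a set that included Cebpb, Cebpd, Csf3, Ptgs2 and Steap4 (camera adjusted p = 5.32e-41, and adjusted p = 0.000483 with an estimated correlation). Among the inflammatory cytokines and growth factors 4 rose, and 9 adjusted over the list alone (camera adjusted p = 5.58e-18, and adjusted p = 7.44e-05 with an estimated correlation). Of 16 regulators of mRNA decay, Zc3h12a and its relative Zc3h12c (0.57 ± 0.14) rose, and 3 adjusted over the list alone (camera adjusted p = 1.06e-07, and adjusted p = 7.44e-05 with an estimated correlation). Junb (0.84 ± 0.17) and Myc (0.43 ± 0.09) rose among 33 immediate-early genes, and 11 adjusted over the list alone (camera adjusted p = 4.09e-13, and adjusted p = 0.0212 with an estimated correlation). Over all comparisons the preset test called 14, 11, 12 and 10 of 27 lists for TNFa in wild-type, TNFa in CIKS-deficient, both cytokines in wild-type and both in CIKS-deficient cells. Of these 6, 6, 7 and 6 held with an estimated correlation: NF-kB feedback and target genes, ELR+ CXC chemokines, other chemokines, inflammatory cytokines, the IL-17 response list and regulators of mRNA decay in all 4, and immediate-early genes with both cytokines in wild-type cells. With both cytokines the cartilage markers again had a lower median in wild-type cells (-0.37, camera adjusted p = 0.042, and adjusted p = 0.607 with an estimated correlation), not called without WT mock replicate 1, 2, 4 or 5 or WT IL17+TNFa replicate 1, 2 or 6 (median -0.23 without WT IL17+TNFa replicate 1). Without WT TNFa replicate 2 the preset test did not call the regulators of mRNA decay for TNFa in wild-type cells (adjusted p = 0.0576). No call in the other 10 comparisons held with an estimated correlation. The list tests were not run with the block on the sets, so the estimated correlation includes differences between the sets. Calls lost with it, here and elsewhere, thus do not show that a list did not shift.

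CIKS-deficient cells given both cytokines again raised the TNFa genes. Ccl20 rose by 4.73 ± 0.59, Cxcl2 by 4.43 ± 0.47, Nfkbie by 3.40 ± 0.32, Cxcl10 by 2.96 ± 0.37, Tnfaip3 by 2.63 ± 0.29 and Lif by 1.69 ± 0.23 (SE, n = 6 per group). Ccl2, Sele, Pdgfb, Rnd1, Relb and Birc3 rose by 1.96 to 2.43. Zc3h12a (0.84 ± 0.33), Il6 (1.18 ± 0.41) and Csf2 (2.10 ± 0.81) did not pass over all probe sets in the fit without the sets. The block on the sets gave smaller standard errors, 0.187 for Zc3h12a and 0.18 for Il6 in wild-type cells given IL-17. The changes of Zc3h12a and Il6 in CIKS-deficient cells are large beside errors of that size. These non-calls may therefore depend on the fit, and they do not show that the genes were unchanged. The limma test called 96 probe sets, 91 higher and 5 lower, and 69 of the higher ones were also among the 120 higher in wild-type cells, where independent lists would share 0.242. Of the 18 lower in wild-type cells 1 was among the 5, where independent lists would share 0.002, and the 18 had a median of -0.70 in wild-type and -0.36 in CIKS-deficient cells. The 5 had a median of -1.59 in CIKS-deficient and -0.654 in wild-type cells, so each list fell more in the genotype that selected it. With the block on the sets 383 were called in CIKS-deficient cells, 309 higher and 74 lower, of which 234 and 35 were shared with the 436 and 254 in wild-type cells, where independent lists would share 2.99 and 0.417. Of 30 NF-kB feedback and target genes 15 rose, and 21 adjusted over the list alone (camera adjusted p = 5.71e-81, and adjusted p = 2.56e-09 with an estimated correlation). Of the IL-17 response genes 5 rose, and adjusted over the list alone 9 rose and S100a9 fell (camera adjusted p = 1.97e-19, and adjusted p = 0.0259 with an estimated correlation). With only these 2 groups in the fit 51 probe sets were called.

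**Figure D3:**
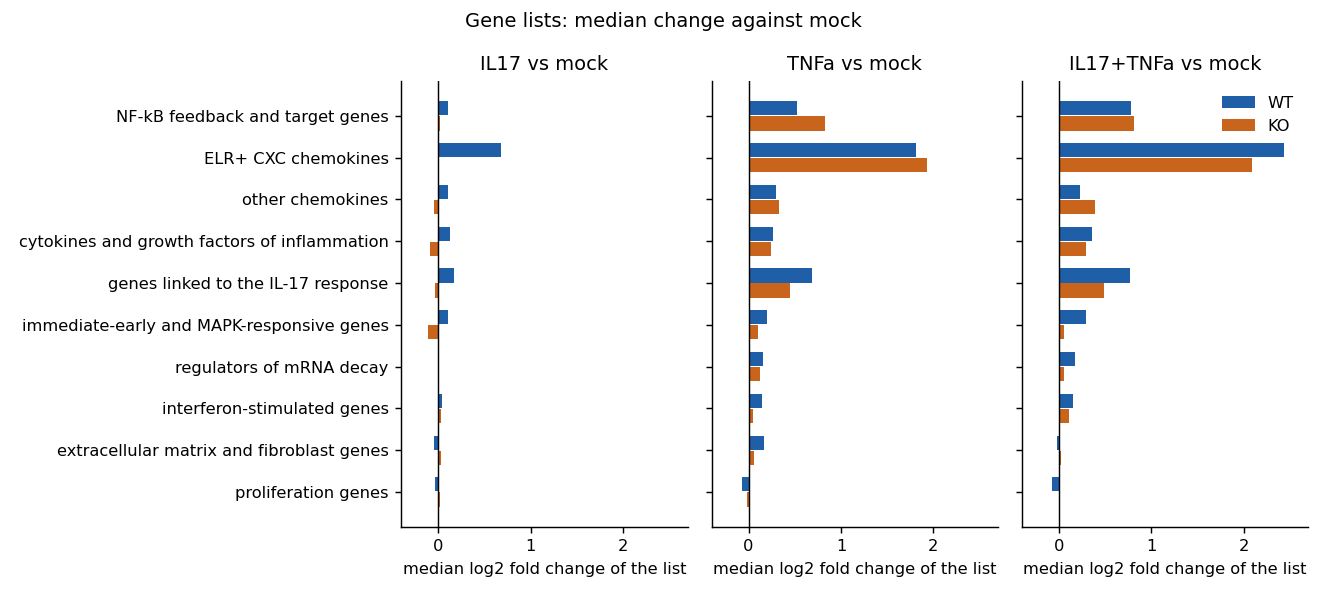
Median log2 fold change against mock (horizontal axis) of 10 gene lists, in wild-type (WT) and CIKS-deficient (KO) cells; each bar is the median over the list's measured genes and starts at 0. The ELR+ CXC chemokines had medians of 1.81 and 1.93 with TNFa and 2.44 and 2.09 with both cytokines, in wild-type and CIKS-deficient cells.

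Adding IL-17 to TNFa in wild-type cells raised Zc3h12a and Nfkbiz. Against TNFa alone, Zc3h12a was higher by a log2 fold change of 2.45 ± 0.33 on one probe set and 1.18 ± 0.21 on the other, and Nfkbiz by 1.63 ± 0.18 and 1.79 ± 0.18 (SE, n = 6 per group). These 4 probe sets were the calls of the limma test (adjusted p = 4.04e-05 for the first Zc3h12a probe set and 1.18e-07 for the first of Nfkbiz), while the third Nfkbiz probe set stood at 0.03 ± 0.12. With a pseudocount of 64 the call was 8 probe sets, these 4 among them, and with the block on the sets 23, 22 higher and 1 lower, a count that 3 of 32 splits within the sets reached, the real one included. Among the 31 IL-17 response genes 2 rose, and 6 adjusted over the list alone, which added the transcription factor gene Cebpd (0.94 ± 0.31), Il6 (1.27 ± 0.41), Csf2 (2.33 ± 0.81) and Cxcl2 (1.30 ± 0.47). Camera gave that list adjusted p = 8.54e-05, adjusted p = 0.846 with an estimated correlation, and 0.0609 without WT IL17+TNFa replicate 5. Lif stood at 0.96 ± 0.23 and passed only when adjusted over the list alone of inflammatory cytokines (2 rose by that count, 0 over all probe sets). Rc3h1 stood at 0.35 ± 0.08 and passed adjusted over the list alone of mRNA decay regulators, where 1 gene rose over all probe sets and 2 over the list. The median of 24 extracellular matrix and fibroblast genes was -0.18, with 0 members called, camera adjusted p = 8.4e-06 and adjusted p = 0.703 with an estimated correlation. Without WT TNFa replicate 2 it was -0.07 and the list was not called (adjusted p = 0.2).

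In CIKS-deficient cells the same addition called 0 probe sets by limma, and 1399 had an unadjusted p under 0.05. Nfkbiz on its first probe set stood at -0.03 ± 0.18, Zc3h12a at 0.20 ± 0.33, Il6 at 0.14 ± 0.41 and Csf2 at 0.50 ± 0.81 (SE, n = 6 per group). The genotype difference in what IL-17 added to TNFa was called for 2 probe sets, both of Nfkbiz, at 1.66 ± 0.25 (limma adjusted p = 0.000668) and 1.94 ± 0.26 (adjusted p = 8.42e-05). With the block on the sets 4 were called, which added 1 of Zc3h12a (limma adjusted p = 6.05e-06) and 1 of Cxcl1 (adjusted p = 0.000631). Without it Zc3h12a differed by 2.25 ± 0.47 (limma adjusted p = 0.274) and passed adjusted over the list alone of IL-17 response genes (adjusted p = 0.000283), so that 1 member of that list differed over all probe sets and 2 over the list. Camera gave it adjusted p = 0.00201, and adjusted p = 0.913 with an estimated correlation. It was not called without KO IL17+TNFa replicate 3 (adjusted p = 0.246), KO TNFa replicate 4 (0.153), WT IL17+TNFa replicate 5 (0.14) or WT TNFa replicate 5 (0.107).

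Departure from additivity, the change with both cytokines beyond the sum of the single changes on the log2 scale, was called for 0 probe sets by limma in either genotype. At an unadjusted p under 0.05 there were 1331 probe sets in wild-type and 1058 in CIKS-deficient cells. Zc3h12a departed by 0.19 ± 0.47 and Nfkbiz by 0.01 ± 0.25 in wild-type cells, and Cxcl1 by -1.73 ± 0.73 (SE, n = 6 per group, limma adjusted p = 1 for Cxcl1). On this scale Cxcl1 had changed by 2.17 with IL-17, 2.46 with TNFa and 2.91 with both.

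Between unstimulated cells of the 2 genotypes, Traf3ip2 was the gene that passed the test, lower in CIKS-deficient cells by a log2 fold change of -0.74 ± 0.12 (SE, n = 6 per group). The limma test called this 1 probe set (adjusted p = 0.00361), which did not pass when only the mock arrays were fitted (limma adjusted p = 0.928). Without KO mock replicate 6 the count was 3. Xist, the RNA that silences an X chromosome in female cells, was high on 4 and low on 2 CIKS-deficient mock arrays, and high on 2, intermediate on 1 and low on 3 wild-type mock arrays, with a difference in the mean of 1.36 ± 1.89 that did not pass. Of 16 macrophage markers all had a lower mean in CIKS-deficient cells, with a median of -0.90, among them Lyz2 (-0.79 ± 0.34) and the complement gene C1qa (-1.33 ± 0.62), and 0 passed over all probe sets or over the list alone. Camera gave the macrophage list adjusted p = 1.14e-13, and adjusted p = 0.338 with an estimated correlation. Lower with it were the medians of 26 interferon-stimulated genes (-0.38, camera adjusted p = 9e-05), the IL-17 response list (-0.43, 0.00336), 14 MHC class I antigen presentation genes (-0.34, 0.00357), the ELR+ CXC chemokines (-0.71, 0.014) and 14 cartilage markers (-0.38, 0.0103), with adjusted p of 0.529 to 0.563 with an estimated correlation. Without WT mock replicate 2 none of these 5 lists was called, with medians of -0.225, -0.214, -0.186, -0.503 and -0.265 and adjusted p of 0.131, 0.258, 0.131, 0.114 and 0.114. The IL-17 response list was not called without KO mock replicate 1 (-0.279) or 2 (-0.327) either, the ELR+ CXC chemokines without KO mock replicate 1 (-0.435) or WT mock replicate 4 (adjusted p = 0.164), and the cartilage markers without WT mock replicate 4 (-0.292) or 5 (-0.264). The preset test also called NF-kB feedback and target genes (median -0.172), other chemokines (-0.162) and smooth muscle and myofibroblast genes (0.0359). None of these calls held with an estimated correlation. The NF-kB list was not called without WT mock replicate 2 (-0.106, camera adjusted p = 0.258). The other chemokines lost their call without any 1 of 5 arrays, and the smooth muscle list without any 1 of 8. Adjusted over the list alone, 3 of the 19 other chemokines were lower, Ccl3 (-1.38 ± 0.45), Ccl4 (-0.62 ± 0.20) and Ccl9 (-1.17 ± 0.32). Immediate-early genes had a higher median (0.16, camera adjusted p = 1.14e-08, and adjusted p = 0.338 with an estimated correlation), which was 0.05 without KO mock replicate 3 (adjusted p = 0.0462).

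The mean log2 level of the macrophage markers was 8.28 ± 0.67 on wild-type mock arrays and 7.36 ± 0.71 on CIKS-deficient mock arrays (SD, n = 6). A two-sided exact permutation test gave p = 0.0368 in mock, 0.0303 with IL-17, 0.0325 with TNFa and 0.0368 with both, and adjusted p = 0.294 in each after Benjamini-Hochberg adjustment over 10 cell type lists in 4 treatments. Arrays of the 4 treatments fell into shared sets, so these 4 tests are not independent and may repeat much the same comparison. In each treatment 1 wild-type array stood far above the other 5, at 9.61 in mock, and without it the mock difference was -0.65 (exact permutation p = 0.0866). None of the 10 cell type lists passed the adjusted exact test in any treatment. The mean level of the fibroblast and matrix list was 11.66 ± 0.28 on CIKS-deficient and 11.79 ± 0.15 on wild-type mock arrays (SD, n = 6).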

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

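The tests of the sets of arrays, of the macrophage markers and of other splits of the arrays were chosen only after the results were seen. For 10 measures in 8 groups of 6 arrays, 80 cases in all, 9 had an array far from the others, where chance gives about 4 if the cases are independent; 4 of the 9 are the macrophage markers below, and these are not. Traf3ip2 was lowest on KO mock replicate 2, at a log2 level of 6.72 against 7.25 for the next. Cxcl1 was lowest on KO TNFa replicate 5, at 9.14 against 11.79. Lif was highest on KO TNFa replicate 4, at 10.35 against 9.85. The GAPDH 3' to 5' ratio was 1.473 on WT mock replicate 1 (next 0.983) and 1.267 on KO IL17 replicate 4 (next 0.964). The response of Nfkbiz to IL-17 differed between genotypes by a log2 fold change of 1.68 and 1.89 on 2 probe sets, and its response to IL-17 added to TNFa by 1.66 and 1.94.

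The mean level of the macrophage markers stood far above the other wild-type arrays on WT mock replicate 3 (9.61, next 8.27), WT IL17 replicate 3 (9.59, next 8.24), WT TNFa replicate 5 (9.66, next 8.27) and WT IL17+TNFa replicate 2 (9.58, next 8.22). The difference between genotypes was not removed by centring every array on its median, with a list median of -0.861, which argues against scaling between arrays. Cells of another type are a candidate source, as a hypothesis: the markers moved together within groups with a mean pairwise correlation of 0.807, against a highest value of 0.184 in 1000 random lists, and abundant ones such as Lyz2 (11.28 in wild-type and 10.49 in CIKS-deficient mock cells) moved with them. None of the 16 markers is in another of the lists, and the labels name no step that would remove such cells. An effect of the genotype cannot be told apart from this, since the adjusted exact permutation p was 0.294 and the labels do not say how many animals the cells came from.

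Arrays of different treatments resembled each other in sets, although the labels name no sets. The arrays of all 4 treatments of a genotype were matched jointly, so that each set held an array of every treatment. This was done in separate parts of 500 probe sets each. Both parts put 36 of 36 treated arrays in the same set, where independent parts would agree for 6. The parts come from the same arrays, so a difference that affects a whole array is seen by both. Their agreement alone thus does not show that the arrays of a set are related. A final match used 500 probe sets from both parts, and over these the mean correlation was 0.765 within sets and -0.148 between them. The matching itself maximised this correlation, so these values add no support for the sets. The replicate numbers do not mark the sets, since 8 arrays were matched to the mock array of their own number. All 12 sets held arrays of 1 class of Xist level, against a highest count of 7 in 10000 random sets (permutation p = 1e-04, the smallest they can give), which argues against array processing batches alone. Cell preparations shared between the treatments of a genotype may account for the sets, as a hypothesis. The 4 arrays with high macrophage markers were all in 1 set. Only dim, called and sex-linked probe sets were left out of the matching, so the macrophage markers could help to form the sets. That these 4 arrays share a set is thus no separate support for the hypothesis.

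Counts of called probe sets were compared with those of 100 splits of the arrays into groups of the same sizes, the real one included. These splits exchange arrays between the sets as well. Few of them called as many probe sets as the real one for IL-17 in wild-type cells (3 called, 2 splits as large, highest other 60), TNFa in wild-type (73, 2 splits, 101) and CIKS-deficient cells (81, 1 split, 74), both cytokines in wild-type (138, 2 splits, 194) and CIKS-deficient cells (96, 1 split, 91), and both against TNFa in wild-type cells (4, 2 splits, 5). So it was for the genotype difference in the IL-17 response (2 called, 1 split, highest other 1) and in IL-17 added to TNFa (2, 2 splits, 3). The split with 60 calls for IL-17, where the real one had 3, points to a structure of the samples, but which one is open. It left all 6 wild-type sets whole on one side or the other, where the median split did so for 2, yet 4 other splits that left all 6 whole called 0 by limma. The split with 101 calls left 4 sets whole, and those with 74, 91 and 194 left 2. Treatments were also exchanged only within the sets (32 splits, or 100 for a genotype difference). No other split then called as many probe sets as the real one in any of these 8 comparisons. The highest others were 2, 7, 23, 14, 19, 1, 1 and 1, in the fit without the sets. With 32 splits the real one is 1 of 32 at best, and the 8 comparisons were read without correction. The sets also came from the same values after the results were seen. Chance is thus an unlikely source of these counts but is not excluded. With the sets as a block as well, no other split called as many in 6 of the 8. The highest others there were 5 for IL-17 in wild-type cells and 1 for the genotype difference in the IL-17 response. In wild-type and CIKS-deficient cells they were 140 and 142 for TNFa and 182 and 152 for both cytokines. For both cytokines against TNFa in wild-type cells 3 of 32 did, the real one included (23 called, highest other 495), so chance cannot be excluded for that blocked count, and for the genotype difference in IL-17 added to TNFa 2 of 100 did (4 called, highest other 5). For CIKS-deficient against wild-type mock cells (1 called, highest other 2) 5 of 100 splits called as many, so the count by itself does not exclude chance, but its 1 gene, Traf3ip2, was lower on every CIKS-deficient array in each treatment (exact permutation p = 0.00216). In the comparisons with 0 calls by limma every split calls at least as many by definition, so the splits cannot test them. The highest others there were 4 for IL-17 in CIKS-deficient cells and 9 for both cytokines against TNFa in these cells. They were 12 for the genotype difference in the TNFa response and 2 for the departure from additivity in either genotype. The real counts of these comparisons at an unadjusted p under 0.05 were 1122, 1399, 1053, 1331 and 1058.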

How the results depend on the processing

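The alternatives were planned, except the block on the sets found in the data and the list tests without each array, which were chosen after the data were seen. Of 633 alternative values of named genes, 611 kept their direction and their side of the threshold, 22 no longer passed and 0 changed direction. These genes were chosen for passing on the same arrays, so a change of direction was unlikely from the start. The filter on dim probe sets removed some of them, with 65 values where each other alternative gave 71. When only the groups compared were fitted, which leaves fewer arrays to estimate the spread, the count of called probe sets was 46 for WT TNFa vs mock (42 shared with the fit to all arrays), 37 in CIKS-deficient cells (36 shared), 81 for both cytokines in wild-type cells (75 shared), 51 in CIKS-deficient cells (46 shared), 1 for the genotype difference in the IL-17 response, and 0 by limma for CIKS-deficient against wild-type mock cells. A pseudocount of 64 gave 8 for both cytokines against TNFa in wild-type cells, and the cause was not tested. Leaving out each array in turn gave 1 to 3 for CIKS-deficient against wild-type mock cells, with 3 without KO mock replicate 6. The ranges were 59 to 85 and 58 to 101 for TNFa in wild-type and CIKS-deficient cells and 104 to 146 and 69 to 104 for both cytokines, and WT mock replicate 1, with its high GAPDH ratio, gave the lowest count in both wild-type comparisons. Of 344 alternative values of list calls, 248 kept their side, 95 no longer passed, 61 of them with an estimated correlation, and 1 reversed. That one was endothelial markers in CIKS-deficient against wild-type mock cells with the filter on dim probe sets (median -0.0993, adjusted p = 0.817 by limma's camera), where the median stayed below 0 while the test pointed upward, and the cause was not tested. When each array was left out in turn, 37 of 86 list calls held throughout and 49 were lost without at least 1 array; 61 medians came nearer to 0 by over 1.5 times without some array, 14 of them with a change of sign. The test reversed without KO mock replicate 3 for immediate-early genes in CIKS-deficient cells given IL-17 (medians from -0.153 to 0.0165), in the genotype difference for TNFa (-0.0244 to 0.185) and in the KO departure from additivity (-0.00569 to 0.19). It reversed for interferon-stimulated genes in CIKS-deficient cells without KO TNFa replicate 4 (-0.0797 to 0.289) and, with both cytokines, without KO IL17+TNFa replicate 4 (-0.105 to 0.248). The causes were not tested. The replicate numbers share only a number. Of 72 same-numbered pairs of arrays 22 correlated above 0.1, and 15 correlated best with their own number, where chance gives 12. With the replicate block the counts were 84 and 80 for TNFa and 146 and 96 for both cytokines in wild-type and CIKS-deficient cells, and those of the other 10 comparisons did not change. With a block on the sets found in the data, which come from the measured values and not from the labels, limma called 12 for IL-17 in wild-type cells, 641 (296 higher, 345 lower) and 344 (274, 70) for TNFa and 690 (436, 254) and 383 (309, 74) for both cytokines in wild-type and CIKS-deficient cells, 23 for both against TNFa in wild-type cells, 8 for the genotype difference in the IL-17 response and 4 for that in IL-17 added to TNFa, each including every probe set called without the block. The other 5 comparisons stayed at 0, and CIKS-deficient against wild-type mock cells could not be fitted, since each set lies within a genotype. With this block 3 of 32 splits within sets, the real one included, called as many as the 23, and the highest other called 495. For the 4, 2 of 100 did, the real one included, and the highest other called 5. In wild-type and CIKS-deficient cells the highest others were 140 and 142 for TNFa and 182 and 152 for both cytokines. Another probe set for Traf3ip2 could not be tried, since the arrays have 1. Signal near background limits dim genes such as Csf2.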

Other observations

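All tests behind explanations were chosen only after the results were seen, and none is added here. Several gene groups outside the inflammatory lists had small shifts in wild-type cells given TNFa. MHC class I antigen presentation genes, which load peptides for display to T cells, had a median log2 fold change of 0.22 with 13 of 14 above 0. Extracellular matrix and fibroblast genes had a median of 0.17, matrix proteases and their inhibitors 0.17, smooth muscle and myofibroblast genes 0.10 and interferon-stimulated genes 0.15. No member of these 5 lists passed limma's test over all probe sets or adjusted over the list alone, where 2990 probe sets of the comparison had an unadjusted p under 0.05. Camera called each of them (adjusted p = 5.57e-06, 7.87e-05, 0.0127, 0.00151 and 0.0167), with adjusted p = 0.188, 0.35, 0.348, 0.188 and 0.838 with an estimated correlation. Without WT TNFa replicate 2 the 5 medians were 0.16, 0.03, 0.08, 0.10 and -0.05, and camera called the MHC list alone of the 5 (adjusted p = 0.00445, against 0.2, 0.349, 0.0511 and 0.889). The proteases were not called without WT mock replicate 1 either (0.153), nor the interferon-stimulated genes without WT TNFa replicate 5 (0.0549) or WT mock replicate 1, 4 or 5 (0.139 to 0.226). In CIKS-deficient cells given TNFa, Fas was again higher, by 1.32.

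Other lists were not called in wild-type cells given TNFa. Their median log2 fold changes were -0.07 for 22 proliferation genes, 0.00 for 16 unfolded protein response genes, -0.09 for 16 cholesterol biosynthesis genes, -0.03 for 24 components of IL-17 and TNF receptor signalling and 0.04 for 4 sex-linked genes. Among markers of other cell types they were 0.06 for macrophage, -0.14 for endothelial, -0.20 for epithelial, 0.07 for neural, 0.03 for skeletal muscle, -0.26 for cartilage, 0.00 for adipocyte and -0.14 for erythroid markers. The mean and the test of the adipocyte list (-0.11) and the mean of the unfolded protein response list (-0.01) lay below 0, and the mean of the receptor list (-0.03) lay below 0 where its test pointed upward. In CIKS-deficient against wild-type mock cells, endothelial (-0.35), epithelial (-0.50) and cholesterol biosynthesis genes (-0.18) had lower medians and HOX genes (0.11) a higher one, with camera adjusted p = 0.034, 0.044, 0.014 and 0.0183, and adjusted p = 0.563, 0.563, 0.626 and 0.563 with an estimated correlation; with the filter on dim probe sets the endothelial median stayed below 0 while its test pointed upward. Each of these 4 calls was lost without WT mock replicate 2. Endothelial markers lost it also without WT mock replicate 4 or 5 or KO mock replicate 1, 2, 3 or 4, epithelial without WT mock replicate 4, 5 or 6 or KO mock replicate 2, 4, 5 or 6, cholesterol without WT mock replicate 5 or 6 or KO mock replicate 1 or 4, and HOX without WT mock replicate 1 or 4 or KO mock replicate 1, 2 or 5. Without KO mock replicate 1 the cholesterol median was -0.04 and that of HOX genes 0.03, and without WT mock replicate 5 the mean of the endothelial list was -0.23 in place of -0.39.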
